A study of Homo sapiens with 6 samples.

How the data were processed

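Total RNA of 6 samples of the mouse ovarian cancer line ID8, genotype p53-/- Brca2-/-, was sequenced as TruSeq libraries. Per the labels, cells in 6-well plates were transfected with short RNA at 10 nM using a lipid reagent, and RNA was isolated after 48 h with a column kit and DNase digestion. The organism label names human, but gene identifiers are of mouse and the submitters' processing notes name the mouse build mm10, so the data were treated as mouse. Groups were set from the treatment label: sNT8 (control), sG5C and sCAG, 2 libraries each.

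There were 2 deposited tables, of sCAG and of sG5C, each with the same sNT8 libraries. Each held 24648 rows for 24514 gene identifiers, with 134 rows sharing an identifier and 67 symbols standing on more than 1 identifier. The values per library are a normalised signal that the authors deposited without naming its unit. Every deposited value was a whole multiple of 1 step per library, so the read counts were recovered from the deposited values by dividing by that step, with 100% of values whole within 0.001 read. The recovered sNT8 counts were identical between the tables for all 24514 genes. The tables had been scaled separately. The submitters' processing notes name STAR, HTSeq and edgeR, with no versions. The column names resemble DESeq2 output, and no header names the tool. The authors' tables also gave log2 fold changes with standard errors and p-values per the file headers. The authors' adjusted p-values were adjusted over 13978 and 14085 genes but are given for 11562 and 11618, so the tables may hold part of the genes and the recovered totals part of each library. They held 0 mitochondrial rows. The counting mode for strand is not given in the sources used here, so overlapping and antisense genes and near-identical copies are uncertain.

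Before the data were examined, edgeR on counts was planned for a table of counts and limma-trend for normalised values. The files held normalised values, another unit than the counts assumed, so limma-trend (limma 3.58.1, R 4.3.3) was run on log2 of the value plus 1, for genes with values of at least 1 in at least 2 libraries. The 4 libraries of each table were fitted alone with the group as the only term, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. sG5C against sCAG used recovered reads divided by size factors of all 6 libraries, with all 6 in 1 fit. Also chosen then were the gene lists, the alternatives and the rule for the genes named in the text. The rule took, against sNT8, the 8 risen and 8 fallen genes with the largest log2 fold changes among called genes of at least 4 CPM whose libraries did not overlap between groups, leaving out predicted genes, clone names, pseudogenes, microRNA and small nucleolar RNA genes. It also took up to 2 risen and 2 fallen members per list with the smallest p, or the member with the smallest p where none was called, and Trp53 and Brca2. For sG5C against sCAG it took the 5 highest and 5 lowest genes. Genes named outside the rule are said to be so, and some genes that the rule took are not reported here.

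The 26 lists were: interferon-stimulated genes, inflammatory NF-kappaB targets, ATF4 targets, endoplasmic reticulum chaperones, p53 targets, homologous recombination and Fanconi anaemia, mitosis, DNA replication, replication-dependent histones, cytosolic ribosomal proteins, proteasome subunits, spliceosome, RNA polymerase II and transcription elongation, chaperonin and prefoldin, small RNA pathway, apoptosis and necroptosis, cholesterol synthesis, NRF2 targets, heat shock proteins, immediate early genes, extracellular matrix and mesenchymal genes, ovarian surface epithelium and mesothelium, mitochondrially encoded transcripts, and markers of macrophages and leukocytes, endothelium and fibroblasts. They were tested with limma's camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over the lists within a comparison. Members called were counted after adjustment over all genes and over the list alone.

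The responses were correlated across genes beside 100 simulations of unchanged groups. The other settings chosen in advance were edgeR 4.0.16 with another scaling and with no filter, DESeq2 1.42.0, limma-voom, all 6 libraries in 1 fit or the compared ones alone, the replicate number as a block, a pseudocount of 0.1, no filter on low values, a fold change of at least 2, the authors' adjusted p-values, and leaving out each library. Chosen after the data had been seen were edgeR with its default scaling, edgeR with the block, values of at least 10, an exchanged numbering, and the correlation of the responses against different sNT8 libraries among genes of at least 4 CPM. Human transcripts (GENCODE release 29) stood in for mouse transcripts, matched by gene symbol, for genes of at least 1 CPM. Permutation tests drew 100000 resamples and were two-sided, so that 1e-05 is the smallest p they can give. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, biopython 1.88 and matplotlib 3.10.9 were used.

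The fits were tested on simulated data with 200 changed genes, 50 at each fold. Changed genes were drawn only from genes above a minimum mean read count, so detection near the floor was not measured. In simulated sCAG against sNT8 (14541 genes) limma called 28%, 78%, 94% and 100% of genes changed 1.2, 1.5, 2 and 4 times, and 1.19% of its calls were unchanged genes. In simulated sG5C against sNT8 (14545 genes) these were 16%, 82%, 98% and 100%, with 3.51%, and in simulated sG5C against sCAG (15137 genes) 24%, 76%, 96% and 100%, with 3.47%. A simulated list of 25 genes shifted by -0.45 in sCAG against sNT8 had an adjusted p of 3.96e-37 by camera. It had 0.118 by camera with an estimated correlation and 0.0397 by fry. Camera called 0 of 24 unchanged lists. Genes were drawn independently there, so false list calls from correlated members could not appear. In the data of sCAG against sNT8 the estimated correlation ran from -0.177 for fibroblast markers to 0.793 for proteasome subunits. The common biological coefficient of variation by edgeR was 5.1% over 11848 genes.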

Results

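RNA from ID8 cells, a mouse ovarian cancer line, was sequenced 48 h after transfection with short RNAs at 10 nM. The cells carried a p53-/- Brca2-/- genotype, called DKO in the labels. The series title describes short RNAs that induce DISE, a form of cancer cell death brought on by loss of transcripts that cells need to survive. There were 3 groups of 2 libraries: the control short RNA sNT8, sG5C and sCAG. The sG5C libraries were named siMxy in their titles and sG5C in their treatment label, and the treatment label set the group. The reads recovered from the tables came to 9699158 and 11348968 for sNT8, 11152820 and 10078422 for sG5C, and 10007797 and 12808992 for sCAG. Between 14649 and 14955 genes had at least 1 read in a library, and the 20 most abundant genes took between 6.22% and 6.43% of the reads. Replicates correlated across genes at r = 0.992 for sNT8 and 0.993 for sG5C and for sCAG on the log2 CPM scale. They differed by more than counting error, with a chi-square per degree of freedom of 3.88, 2.94 and 2.75. The principal component with 42.7% of the variance set sG5C apart from sCAG with sNT8 between them, and the next, with 24.1%, set sNT8 apart from the other groups.

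The genes of the genotype label were read at the gene level, so a deletion of part of a gene cannot be checked from these counts. Trp53 (ENSMUSG00000059552, mm10 chromosome 11, 69580358 to 69591873), which encodes p53, had 350 ± 36.6 normalised reads (SD, n = 2) under sNT8 and 374 ± 149 under sCAG, with a log2 fold change of 0.04 (limma adjusted p = 0.92). The sCAG libraries differed in sign, with a value of 0.46 (limma adjusted p = 0.027) without sCAG replicate 2 and -0.37 (limma adjusted p = 0.15) without sCAG replicate 1. Under sG5C Trp53 had 342 ± 44.9 normalised reads (log2 fold change 0.01, limma adjusted p = 0.99). Brca2 (ENSMUSG00000041147, chromosome 5, 150522620 to 150570146), a gene of homologous recombination, had 1026 ± 16.9 normalised reads under sNT8 and 1072 ± 15.0 under sCAG (log2 fold change 0.06, limma adjusted p = 0.70). Brca2 stood at 841 ± 56.2 under sG5C against 998 ± 14.4 under sNT8, a log2 fold change of -0.25 (limma adjusted p = 0.037, edgeR adjusted p = 0.015). That call ended with a pseudocount of 0.1 or no filter on low values (limma adjusted p = 0.059 each). It was lost under DESeq2 (adjusted p = 0.063), with the replicate number as a block (limma adjusted p = 0.12) and by the authors' adjusted p (0.072). It also ended without any 1 of the libraries, with limma adjusted p = 0.099 without sNT8 replicate 1, 0.050 without sNT8 replicate 2, 0.074 without sG5C replicate 1 and 0.40 without sG5C replicate 2.

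sCAG against sNT8 asked which transcripts changed after transfection of a short RNA named for CAG. Prkcsh (ENSMUSG00000003402, chromosome 9, 22002987 to 22014245), the beta subunit of the glucosidase that trims N-glycans in the endoplasmic reticulum, fell from 1847 ± 18.9 to 365 ± 44.2 normalised reads (SD, n = 2), a log2 fold change of -2.34 ± 0.09 (SE, limma adjusted p = 6.3e-22). Rpn1 (ENSMUSG00000030062, chromosome 6, 88084472 to 88105304), a subunit of the oligosaccharyltransferase that attaches those glycans, fell from 3581 ± 163 to 807 ± 32.7 (log2 -2.15 ± 0.07, limma adjusted p = 3.2e-22). Cpd (ENSMUSG00000020841, chromosome 11, 76777207 to 76847008), the gene of carboxypeptidase D, fell from 2965 ± 87.6 to 724 ± 1.72 (log2 -2.03 ± 0.07, limma adjusted p = 6.3e-22). Sephs2 (ENSMUSG00000049091, chromosome 7, 127271878 to 127274059), which makes the selenium donor for selenoproteins, fell from 494 ± 14.8 to 116 ± 5.82 (log2 -2.08 ± 0.12, limma adjusted p = 7.3e-16).

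Ptgis, the gene of prostacyclin synthase, had a log2 fold change of -1.92, the integrin subunit gene Itgav one of -1.91 and Ghdc one of -1.84, all called by limma. Lars2, the mitochondrial leucyl-tRNA synthetase gene, also met the rule for the largest falls, with a log2 fold change of -2.34, but its sNT8 libraries held 999 and 6608 normalised reads against 499 and 517 under sCAG. Its value was -0.97 without sNT8 replicate 2 and -3.70 without sNT8 replicate 1, and it was not called by the authors' adjusted p (0.11). The rises were smaller. Ptbp2 (ENSMUSG00000028134, chromosome 3, 119718741 to 119783388), the neuronal polypyrimidine tract binding protein that regulates splicing, rose from 831 ± 15.8 to 1853 ± 57.4 (log2 1.16 ± 0.08, limma adjusted p = 1.3e-14). Pakap rose by 1.18, the Myc antagonist gene Mxd4 by 0.99, the phosphatidylcholine transfer protein gene Pctp by 0.95 and the histone demethylase gene Kdm7a by 0.92. Gpat3, Kctd21 and Ube2l6 rose by 0.93, 0.93 and 0.92, but these calls ended under DESeq2 (adjusted p = 0.088, 0.13 and 0.075) and without single libraries, and those of Gpat3 and Kctd21 by the authors' adjusted p (0.062 and 0.10). The limma adjusted p of Gpat3 was 0.11 without sNT8 replicate 2, where its log2 fold change was 0.62, and 0.22 without sCAG replicate 1. That of Kctd21 was 0.083 without sNT8 replicate 2, 0.29 without sCAG replicate 1 and 0.052 without sCAG replicate 2. That of Ube2l6 was 0.10 without sNT8 replicate 1, where its log2 fold change was 0.59, and 0.20 without sCAG replicate 2.

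Genes of cholesterol synthesis fell together in sCAG against sNT8. Of 25 members tested, 21 were lower and 0 higher, and the count adjusted over the list alone was also 21, with a median log2 fold change of -0.45. Hsd17b7 fell by 1.47 and Hmgcs1, which condenses acetoacetyl-CoA to HMG-CoA, by 0.85. The count stood at 15 to 20 when any 1 library was left out. The list passed limma's camera test (adjusted p = 3.6e-23), a call lost with adjusted p = 0.95 with an estimated correlation, where the unadjusted p was 0.054. By fry the adjusted p was 0.0855 (unadjusted 0.0068). In the simulated comparison, camera with an estimated correlation also missed a list of 25 genes shifted by -0.45 (adjusted p = 0.118). A list call lost in that setting therefore does not show that the list was unchanged. Endoplasmic reticulum chaperones were lower for 7 of 25 members, or 8 adjusted over the list alone, with Creld2 at -0.83 and the disulfide isomerase gene Pdia6 at -0.55 (limma camera adjusted p = 7.0e-05, adjusted p = 0.95 with an estimated correlation). Without sCAG replicate 1 the chaperone count was 3. Heat shock proteins were lower for 6 of 20, or 7 adjusted over the list alone, among them Hsph1 at -0.53 and Hspa4l at -0.50 (limma camera adjusted p = 3.7e-04, adjusted p = 0.95 with an estimated correlation). That count was 10 without sNT8 replicate 1, 4 without sNT8 replicate 2, 2 without sCAG replicate 1, which ended the list call at adjusted p = 0.086, and 3 without sCAG replicate 2.

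In sCAG against sNT8, homologous recombination and Fanconi anaemia genes had 7 of 33 members lower and 1 higher, or 8 and 1 adjusted over the list alone (limma camera adjusted p = 0.0057, adjusted p = 0.95 with an estimated correlation). Atm, the DNA damage kinase gene, fell by 0.44. The count of lower members was 2 without either sCAG library, and the list call ended at adjusted p = 0.062 without sNT8 replicate 1 and 0.14 without sCAG replicate 2. Extracellular matrix and mesenchymal genes had 8 of 35 lower and 2 higher, or 9 and 2 adjusted over the list alone, with Thbs1 (thrombospondin) at -0.93 (limma camera adjusted p = 0.020, adjusted p = 0.95 with an estimated correlation). Without sCAG replicate 1 that count was 4 and the list's adjusted p was 0.086. Inflammatory NF-kappaB targets had 5 of 25 lower and 1 higher, or 6 and 1 adjusted over the list alone, with the cytokine gene Csf1 at -0.70 and Nfkb1 at -0.35 (limma camera adjusted p = 0.020, adjusted p = 0.95 with an estimated correlation). That list call ended at adjusted p = 0.096 without sNT8 replicate 1, 0.075 without sCAG replicate 1, where 2 members were lower, and 0.062 without sCAG replicate 2, and 3 members were lower without sNT8 replicate 2. Cytosolic ribosomal protein genes had a median of 0.09 and passed the list test as higher (limma camera adjusted p = 0.020, adjusted p = 0.95 with an estimated correlation), although 1 of 79 members was higher and 1 lower, or 0 and 1 adjusted over the list alone. The lower member was Rpl14, at -1.32. The ribosomal call ended without sNT8 replicate 1 (adjusted p = 0.49) and without sCAG replicate 2 (adjusted p = 0.98), and without sNT8 replicate 2 there were 9 higher members.

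The other lists did not pass the list test in sCAG against sNT8, though members of them did. ATF4 targets had 4 higher and 2 lower of 36 (5 and 2 adjusted over the list alone), with the stress-response gene Nupr1 at 0.85 and Ddit4 at -0.55. Immediate early genes had 5 higher and 1 lower of 21 (8 and 1 adjusted over the list alone), with Jun at 0.48 and Klf4 at 0.46. DNA replication genes had 5 lower of 50 (5 adjusted over the list alone), with cyclin E1 gene Ccne1 at -0.95 and the helicase gene Mcm7 at -0.46. The p53 targets had 2 higher and 2 lower of 27 (2 and 2 adjusted over the list alone), and mitosis genes had 3 and 3 of 40 (3 and 4). Among apoptosis and necroptosis genes 2 were higher and 2 lower of 28 (6 and 4 adjusted over the list alone), with Bak1, a pore-forming protein of mitochondrial apoptosis, at 0.68 and the necroptosis kinase gene Ripk1 at -0.58. Of 20 genes of the small RNA pathway 2 were higher and 3 lower (2 and 4 adjusted over the list alone), with Tarbp2, a partner of Dicer, at -0.58. Spliceosome genes had 4 higher of 38 (4 adjusted over the list alone), RNA polymerase II and transcription elongation genes 3 lower of 27 (1 higher and 3 lower adjusted over the list alone), and replication-dependent histones 1 higher and 3 lower of 60 (0 and 1). Proteasome subunits had 1 higher of 32, interferon-stimulated genes 1 higher of 45, NRF2 targets 1 lower of 22, the chaperonin and prefoldin list 1 lower of 14, and ovarian surface epithelium and mesothelium genes 4 lower of 17. Adjusted over the list alone these were 0, 0, 1, 1 and 4. The limma camera adjusted p of these lists ran from 0.051 for DNA replication to 0.89, and all were 0.95 with an estimated correlation. Leaving out an sCAG library lowered at least 1 of the counts of every list in this paragraph, for example to 0 for the spliceosome without either. Leaving out an sNT8 library moved several of them too. Without sNT8 replicate 1 there were 2 higher and 4 lower ATF4 targets, 4 and 2 immediate early genes, 1 and 3 p53 targets, 2 and 5 mitosis genes, 1 and 3 apoptosis and necroptosis genes, 3 and 2 spliceosome genes, 0 and 3 histones, 0 and 2 proteasome subunits, 0 and 3 interferon-stimulated genes, 0 and 3 NRF2 targets, and 1 and 3 of the chaperonin and prefoldin list. Without sNT8 replicate 2 there were 5 higher and 0 lower proteasome subunits, 2 and 1 p53 targets, 5 and 2 mitosis genes, 4 and 2 apoptosis and necroptosis genes, 2 and 1 genes of the small RNA pathway, 2 and 2 histones, 1 and 4 DNA replication genes, 1 and 2 RNA polymerase II and transcription elongation genes, and 1 and 0 of the chaperonin and prefoldin list.

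Markers of other cell types were near the limit of detection. Of 5 macrophage and leukocyte markers tested in sCAG against sNT8, which averaged 2.17 CPM, Fcgr3 was called lower, at 8.81 and 2.96 normalised reads in the sNT8 libraries and 0 in both sCAG libraries. That call ended without sCAG replicate 1 (limma adjusted p = 0.099) or replicate 2 (0.12), and without either sNT8 library no member was called. DESeq2 gave Fcgr3 no adjusted p. None of 5 endothelial and 5 fibroblast markers, which averaged 2.01 and 1.29 CPM, passed by limma or by edgeR, and 0 and 1 had an unadjusted limma p under 0.05. However, 1 fibroblast marker was called higher by limma without sNT8 replicate 1 or without sNT8 replicate 2, and by edgeR with no filter on low counts. The limma camera adjusted p was 0.90 for the macrophage and leukocyte list, 0.89 for the endothelial and 0.28 for the fibroblast list, all 0.95 with an estimated correlation. Median and mean differed in sign for the macrophage and leukocyte markers (0.26 and -0.29), as they did for apoptosis and necroptosis (0.04 and -0.03) and the small RNA pathway (0.01 and -0.01). Mitochondrially encoded transcripts were not analysed here, since 0 of the 13 listed had a value.

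Of 14435 genes tested by limma in sCAG against sNT8, 723 were higher and 923 lower at an adjusted p under 0.05, so that 43.9% of the 1646 calls were higher. DESeq2 on the recovered reads gave 1150 calls with 33.6% higher. At a fold change of at least 2 there were 8 higher and 114 lower genes. Without sCAG replicate 1 there were 780 calls (34.1% higher) and without replicate 2 there were 773 (30.8% higher), and without sNT8 replicate 2 there were 1847 (55.0% higher). Nothing in the labels says that replicates came from separate cultures. All p-values, above and below, thus measure the spread between these samples only, which may be technical.

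**Figure D1:**
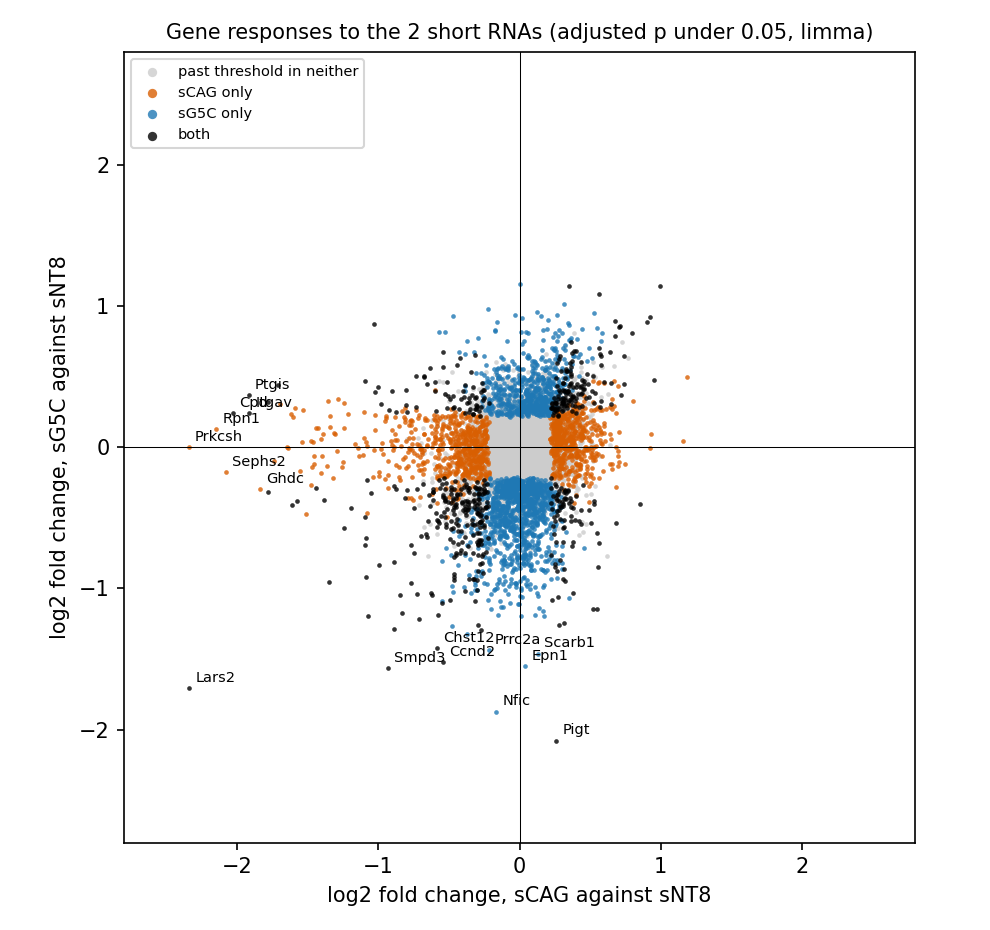
Log2 fold change under sCAG (horizontal axis) and under sG5C (vertical axis), each against sNT8, for 9997 genes of at least 4 CPM in mean over the libraries of each comparison, 9996 of them inside the axes. Colours mark genes past the limma threshold under sCAG, under sG5C, under both or under neither, and the genes with the largest falls are named.

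sG5C against sNT8 asked the same question of the other short RNA. Pigt (ENSMUSG00000017721, chromosome 2, 164497524 to 164508301), a subunit of the transamidase that attaches glycosylphosphatidylinositol anchors to proteins, fell from 674 ± 8.54 to 159 ± 14.1 normalised reads (SD, n = 2), a log2 fold change of -2.08 ± 0.11 (SE, limma adjusted p = 7.7e-18). Nfic (ENSMUSG00000055053, chromosome 10, 81396190 to 81427173), a transcription factor gene of the nuclear factor I family, fell from 5227 ± 13.0 to 1426 ± 23.5 (log2 -1.87 ± 0.08, limma adjusted p = 5.2e-22). Ccnd2 (ENSMUSG00000000184, chromosome 6, 127125708 to 127151048), which encodes the cell cycle entry protein cyclin D2, fell from 7625 ± 569 to 2647 ± 93.4 (log2 -1.52 ± 0.08, limma adjusted p = 4.0e-18). Neat1 (ENSMUSG00000092274, chromosome 19, 5824709 to 5845478), the long noncoding RNA that scaffolds paraspeckles, rose from 8075 ± 2258 to 17474 ± 1157 (log2 1.14 ± 0.11, limma adjusted p = 1.2e-10).

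Under sG5C the neutral sphingomyelinase gene Smpd3 had a log2 fold change of -1.56, the endocytic adaptor gene Epn1 -1.55, the high-density lipoprotein receptor gene Scarb1 -1.46, Prrc2a -1.44 and the chondroitin sulfotransferase gene Chst12 -1.42, all called by limma. Among the rises, Fxyd4 reached a log2 fold change of 1.15, Mxd4 1.14, Slco2a1, a prostaglandin transporter gene, 1.13, and Trp53inp1 1.08. Bicdl2 rose by 1.01, the integrin subunit gene Itgb3 by 0.98 and Polr3g, a subunit of RNA polymerase III, by 0.95. The Slco2a1 call ended without sG5C replicate 1 (limma adjusted p = 0.061). The Bicdl2 call ended without sNT8 replicate 2, where its log2 fold change was 0.67 (limma adjusted p = 0.087), without sG5C replicate 2 (0.15) and under DESeq2 (adjusted p = 0.070).

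**Figure D2:**
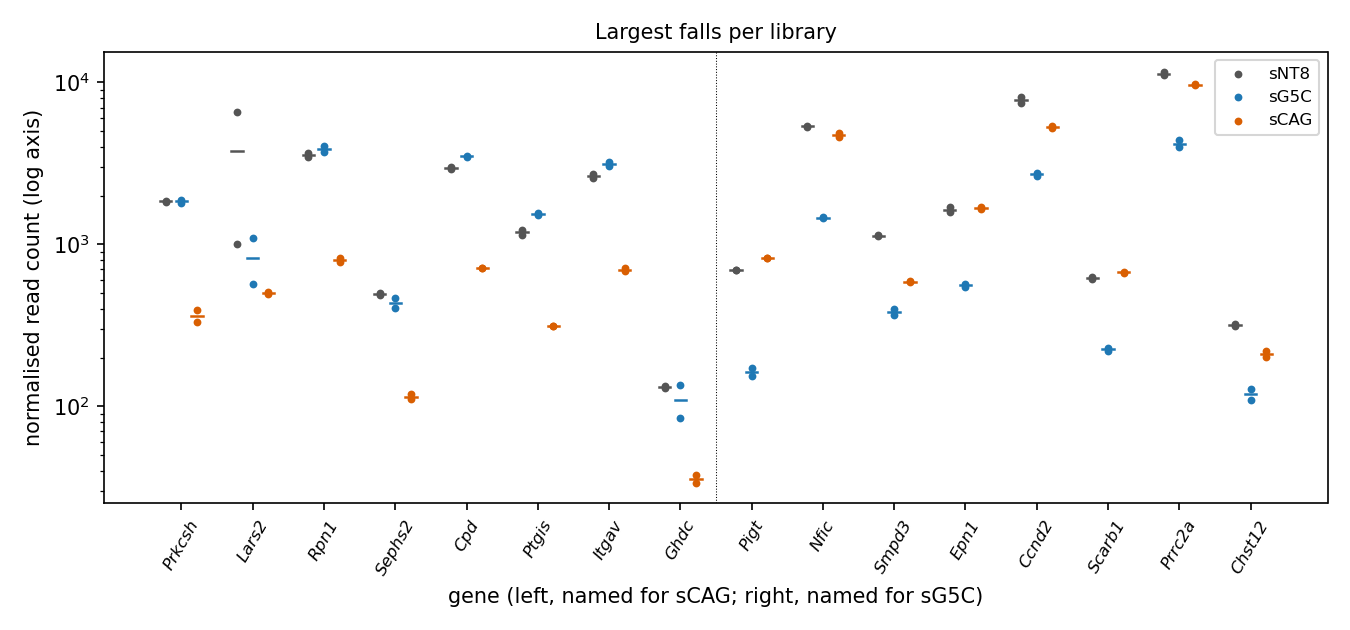
Normalised read counts (log axis) per library of the 8 genes with the largest falls under sCAG (left) and the 8 under sG5C (right), with a point for each of the 2 libraries of sNT8, sG5C and sCAG and a bar at the group mean. The sCAG points of Prkcsh, Rpn1 and Cpd lie below their sNT8 points, as do the sG5C points of Pigt and Nfic, while the sNT8 libraries of Lars2 lie far apart.

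The lists of cytosolic ribosomal proteins and of replication-dependent histones passed the list test as lower in sG5C against sNT8. Of 79 cytosolic ribosomal protein genes 19 were lower, 0 higher and 60 not past the threshold, or 37 lower adjusted over the list alone, with a median of -0.19 (limma camera adjusted p = 5.9e-11, adjusted p = 0.93 with an estimated correlation). Rpl13a fell by 0.72 and Rps19 by 0.37, the latter with a limma adjusted p of 0.14 without sG5C replicate 2. By edgeR 40 members were lower. The number called by limma changed widely when 1 library was left out, where the spread came from the other group alone. Both sG5C libraries had list medians below those of the sNT8 libraries, at -0.154 and -0.228 against -0.034 and 0.034, relative to the sNT8 mean. Of 59 replication-dependent histones 30 were lower and 1 higher, or 35 and 2 adjusted over the list alone, with a median of -0.27 (limma camera adjusted p = 1.6e-08, adjusted p = 0.93 with an estimated correlation). H1f1 and H4c1 fell by 0.56 each. Without sG5C replicate 2 the histone count was 8. Histone and ribosomal protein genes have near-identical copies, so how reads were shared between members is uncertain. The lists were also not tested within classes of coding GC, which correlated with the log2 fold changes under sG5C, as described below. Genes of DNA replication were lower for 11 of 50 members and higher for 1, or 12 and 1 adjusted over the list alone (limma camera adjusted p = 0.0082, adjusted p = 0.93 with an estimated correlation). Tk1 and Rrm2, which make DNA precursors, fell by 0.53 and 0.49. The replication call ended without sNT8 replicate 2 (adjusted p = 0.13) and without sG5C replicate 1 (adjusted p = 0.080), and 7 members were lower without either sG5C library.

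ATF4 targets were lower for 9 of 36 members and higher for 1 in sG5C against sNT8, or 12 and 1 adjusted over the list alone (limma camera adjusted p = 0.0082, adjusted p = 0.93 with an estimated correlation). Atf4 itself, the transcription factor of the amino acid response, fell by 0.60 and the alanyl-tRNA synthetase gene Aars by 0.64. That list call ended without sNT8 replicate 2 (adjusted p = 0.12) and without sG5C replicate 2 (adjusted p = 0.12), and 5 members were lower without either sG5C library. Cholesterol synthesis genes were lower for 9 of 25 and higher for 0, or 11 adjusted over the list alone, with a median of -0.17 (limma camera adjusted p = 0.0014, adjusted p = 0.93 with an estimated correlation). Dhcr7, the last reductase of the pathway, fell by 0.77 and Nsdhl by 0.56. The cholesterol count was 5 without sG5C replicate 1 and 4 without sG5C replicate 2. NRF2 targets were higher for 4 of 22 and lower for 1, or 4 and 1 adjusted over the list alone (limma camera adjusted p = 0.0024, adjusted p = 0.93 with an estimated correlation). The ferritin light chain gene Ftl1 rose by 0.51 and the glutathione reductase gene Gsr by 0.30, the latter with a limma adjusted p of 0.085 without sG5C replicate 1 and 0.076 without sG5C replicate 2. That list call ended without sG5C replicate 1 (adjusted p = 0.15), where 1 member was higher, and 7 were higher without sNT8 replicate 2 and 2 without sG5C replicate 2. In the small RNA pathway 6 of 20 genes were higher and 1 lower, or 8 and 1 adjusted over the list alone (limma camera adjusted p = 0.033, adjusted p = 0.93 with an estimated correlation). Tnrc6a, a partner of Argonaute proteins, rose by 0.83 and the decapping gene Dcp2 by 0.42. In contrast, Drosha, the nuclease that starts microRNA processing, fell by 0.93. With the replicate number as a block the small RNA list did not pass camera. The small RNA call ended without sNT8 replicate 1 (adjusted p = 0.053), sG5C replicate 1 (0.10) or sG5C replicate 2 (0.12), and 2 members were higher without either sG5C library.

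The remaining lists did not pass the list test in sG5C against sNT8. The p53 targets had 2 higher and 5 lower of 27 (5 and 5 adjusted over the list alone), with the cell cycle inhibitor gene Cdkn1a at 0.85 and Trp53inp1 at 1.08. Spliceosome genes had 2 higher and 4 lower of 38 (2 and 4 adjusted over the list alone), with Sf3a2 at -1.06 and Sf3b4 at -0.75. Apoptosis and necroptosis genes had 5 higher and 4 lower of 29 (5 and 5 adjusted over the list alone), with Bmf at 0.58 and Bak1 at -0.54. Mitosis genes had 3 higher and 8 lower of 40 (4 and 8 adjusted over the list alone), with the F-box gene Ccnf at -0.47. Homologous recombination and Fanconi anaemia genes had 1 higher and 5 lower of 33 (1 and 6 adjusted over the list alone), and endoplasmic reticulum chaperones 3 and 4 of 25 (7 and 6). Extracellular matrix and mesenchymal genes had 3 higher and 4 lower of 34 (5 and 7), with the gelatinase gene Mmp2 at 0.81, and ovarian surface epithelium and mesothelium genes 2 and 3 of 15 (2 and 3). Inflammatory NF-kappaB targets had 1 higher and 3 lower of 26 (1 and 3), immediate early genes 1 and 3 of 21 (1 and 3), heat shock proteins 0 and 3 of 21 (0 and 3), and interferon-stimulated genes 1 and 2 of 44 (1 and 1). RNA polymerase II and transcription elongation genes had 1 higher and 2 lower of 27 (1 and 2), proteasome subunits 1 and 0 of 32 (0 and 0), and the chaperonin and prefoldin list 0 and 1 of 14 (0 and 0). None of 5 macrophage and leukocyte, 4 endothelial and 5 fibroblast markers passed by limma or by edgeR, with 1, 1 and 0 at an unadjusted limma p under 0.05. However, 1 macrophage and leukocyte marker was called higher by limma without sNT8 replicate 1 or among values of at least 10, and by edgeR with no filter on low counts. The limma camera adjusted p of these lists ran from 0.21 for heat shock proteins to 0.85. With an estimated correlation none of the 25 lists was below an adjusted p of 0.928, and 0 had an unadjusted p under 0.05. For the immediate early genes the median (-0.03) and the mean (0.03) differed in sign. Leaving out an sG5C library lowered at least 1 of the counts of every list above from p53 targets to the chaperonin and prefoldin list, for example to 0 for lower recombination genes without sG5C replicate 1. Without sNT8 replicate 1 there were 2 higher and 4 lower apoptosis and necroptosis genes, 1 and 4 spliceosome genes, 0 and 8 mitosis genes, 1 and 2 recombination genes, 1 and 2 ovarian surface epithelium and mesothelium genes, 1 and 5 NF-kappaB targets, 1 and 5 immediate early genes, 0 and 6 heat shock proteins, 1 and 1 interferon-stimulated genes, 0 and 0 proteasome subunits, and 0 and 5 of the chaperonin and prefoldin list. Without sNT8 replicate 2 there were 6 higher and 3 lower p53 targets, 6 and 1 endoplasmic reticulum chaperones, 6 and 5 extracellular matrix and mesenchymal genes, 4 and 2 apoptosis and necroptosis genes, 3 and 2 immediate early genes, 0 and 5 recombination genes, 0 and 3 NF-kappaB targets, 1 and 3 heat shock proteins, 1 and 0 interferon-stimulated genes, 2 and 2 RNA polymerase II and transcription elongation genes, and 1 and 0 of the chaperonin and prefoldin list.

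**Figure D3:**
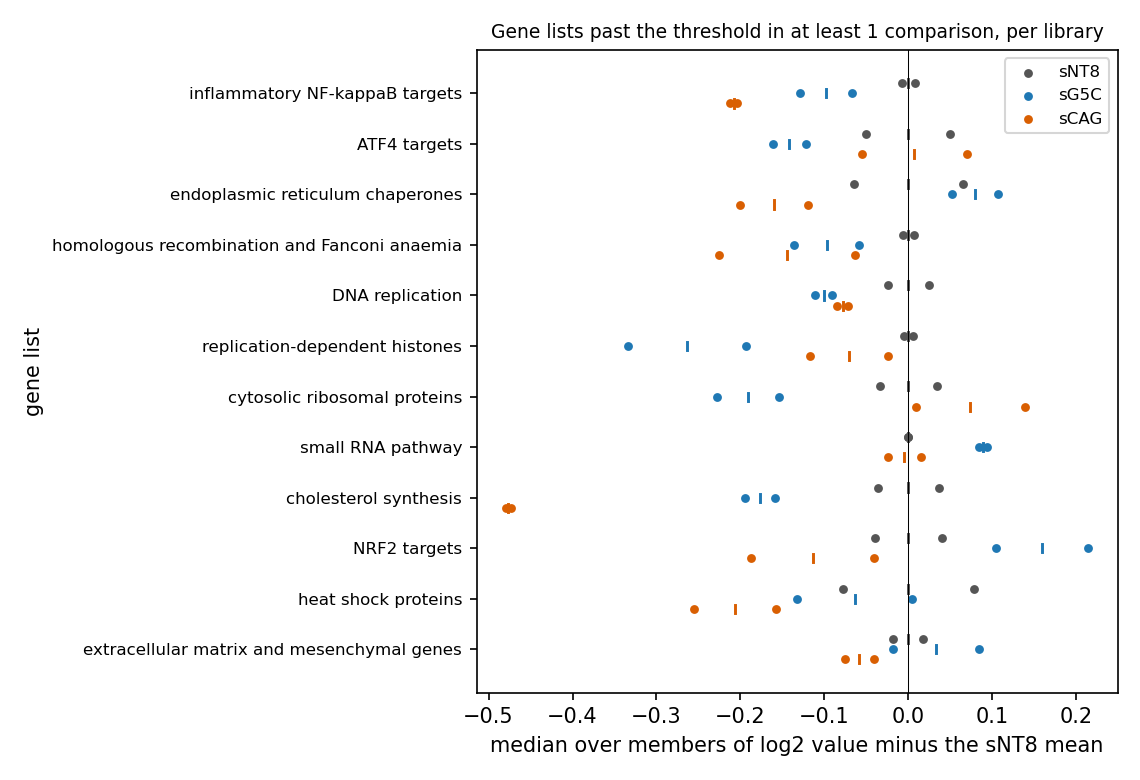
Median over the members of each gene list of the log2 value minus the mean of the sNT8 libraries, with a point per library and a bar at the mean of each group, for the 12 lists past the camera threshold in at least 1 comparison. For cholesterol synthesis the sCAG libraries stand at -0.48 and -0.47 and the sG5C libraries at -0.19 and -0.16.

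In sG5C against sNT8 limma tested 14548 genes, of which 867 were higher and 1352 lower, so that 39.1% of the 2219 calls were higher. A fold change of at least 2 was reached by 60 higher and 88 lower genes. The balance of higher and lower calls moved toward even without sNT8 replicate 2 and away from it without sNT8 replicate 1. The number of calls fell to 1209 (27.6% higher) without sG5C replicate 1 and to 1331 (33.2% higher) without sG5C replicate 2.

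sG5C against sCAG tested the difference between the short RNAs itself, with reads scaled over all 6 libraries. The genes furthest apart included several with the largest falls against sNT8. Prkcsh was higher under sG5C (1842 ± 58.3 normalised reads, SD, n = 2) than under sCAG (361 ± 44.6), a log2 difference of 2.35 ± 0.08 (SE, limma adjusted p = 6.6e-16), followed by Ptgis at 2.30, Rpn1 at 2.29, Cpd at 2.28 and Itgav at 2.17. Pigt was lower under sG5C (163 ± 13.8) than under sCAG (821 ± 2.82), a log2 difference of -2.32 ± 0.09 (SE, limma adjusted p = 1.1e-14), followed by Nfic at -1.69, Mospd3 at -1.68, Wbp2 at -1.65 and Epn1 at -1.58.

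Several lists differed between the short RNAs. The members named for them here were chosen after their values were seen. In sG5C against sCAG, 64 of 79 cytosolic ribosomal protein genes were lower and 1 higher, or 67 and 1 adjusted over the list alone, with a median of -0.25 (limma camera adjusted p = 7.0e-17, adjusted p = 0.88 with an estimated correlation). The higher member was Rpl14, at 1.12, and the ribosomal count was 20 without sG5C replicate 2 and 15 without sCAG replicate 2. Of 60 replication-dependent histones 22 were lower and 1 higher, or 26 and 1 adjusted over the list alone (limma camera adjusted p = 8.1e-05, adjusted p = 0.88 with an estimated correlation), with 6 lower without sG5C replicate 2 and 4 without sCAG replicate 2. ATF4 targets were lower for 14 of 36 and higher for 2, or 15 and 3 adjusted over the list alone, with Nupr1 at -1.25 (limma camera adjusted p = 0.0037, adjusted p = 0.88 with an estimated correlation). Cholesterol synthesis genes were higher for 15 of 25 and lower for 1, or 16 and 1 adjusted over the list alone, with Hsd17b7 at 1.53 and the lower member, Dhcr7, at -0.49 (limma camera adjusted p = 1.1e-06, adjusted p = 0.88 with an estimated correlation). Endoplasmic reticulum chaperones were higher for 13 of 25 and lower for 1, or 15 and 2 adjusted over the list alone, with Creld2 at 1.10 (limma camera adjusted p = 1.0e-04, adjusted p = 0.88 with an estimated correlation), and 7 were higher without sG5C replicate 1 or without sCAG replicate 1. NRF2 targets were higher for 11 of 22 and lower for 1, or 15 and 1 adjusted over the list alone, with Gclm, a subunit of the enzyme that starts glutathione synthesis, at 0.69 (limma camera adjusted p = 4.2e-05, adjusted p = 0.88 with an estimated correlation), and 7 were higher without sG5C replicate 1. The small RNA pathway was higher for 8 of 20 and lower for 1, or 8 and 1 adjusted over the list alone, with Tnrc6a at 0.67 (limma camera adjusted p = 0.031, adjusted p = 0.88 with an estimated correlation), a call that ended without sCAG replicate 2 (adjusted p = 0.0998). Extracellular matrix and mesenchymal genes were higher for 10 of 35 and lower for 2, or 10 and 5 adjusted over the list alone. Thbs1 stood at 0.84, and the list's limma camera adjusted p was 0.046 (adjusted p = 0.88 with an estimated correlation). The list call was lost with the replicate number as a block. That call ended without sG5C replicate 1 (adjusted p = 0.11) and without sCAG replicate 1 (adjusted p = 0.080), and 4 members were lower without sNT8 replicate 1 and 3 without sNT8 replicate 2 or sG5C replicate 1.

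In sG5C against sCAG the other lists had limma camera adjusted p values from 0.14, for immediate early genes, to 0.79. Among them, median and test differed in sign for proteasome subunits (median -0.00, test higher), ovarian surface epithelium and mesothelium (-0.17, test higher) and endothelial markers (0.08, test lower), and apoptosis and necroptosis had a median of 0 with a mean of 0.11. By fry, which tests whether a list's genes move one way on balance, cholesterol synthesis and inflammatory NF-kappaB targets passed, each at an adjusted p of 0.025. Of 15042 genes tested by limma 1663 were higher and 1933 lower under sG5C, and 221 and 99 at a fold change of at least 2. The 3596 calls became 2396 without sCAG replicate 1 and 2300 without sCAG replicate 2.

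The responses to the short RNAs were compared across genes, which are not independent replicates. Over 14139 genes the log2 fold changes of sCAG and sG5C against sNT8 had a Pearson r of 0.384, a Spearman rho of 0.296 and a covariance of 0.0729. Both share the sNT8 libraries, and 100 simulations of unchanged groups against the same controls gave a mean r of 0.513 and a covariance of 0.0602, so the covariance exceeded the simulated one by 0.0128. Among 10061 genes of at least 4 CPM in mean over all 6 libraries r was 0.188, against a simulated mean of 0.509. For these genes the covariance was 0.0147 against 0.00795 simulated. With each response taken against a different sNT8 library r was -0.00108 and 0.00996, against -0.00271 simulated (SD 0.0148). The covariance there was -0.000286 and 0.00261, within the simulated range of -0.00598 to 0.00590. With the same controls the covariance of 0.0729 lay above the highest simulated one of 0.0647. The simulation gave each gene the same spread in all groups, but sNT8 replicates differed most, at a chi-square per degree of freedom of 3.88. It was 2.94 for sG5C and 2.75 for sCAG. That excess may thus come from sNT8 noise, and over all genes it does not show a shared response. Among the genes of at least 4 CPM, a test chosen after the data had been seen, r was 0.0788 and 0.0418 against different sNT8 libraries, and the covariance was 0.00679 and 0.00373, above the highest simulated one of 0.000662. Calls were shared for 135 genes higher under both and 225 lower under both, against 44.2 and 88.3 for independent lists of the same sizes. The simulation, which holds no effects, gave a mean of 0.05 in each direction and does not measure sharing between changed groups. There were 81 genes higher under sCAG and lower under sG5C, against 69.0 for independent lists, and 71 lower under sCAG and higher under sG5C, against 56.5. The values for independent lists spread the calls over all 14139 genes. However, 911 of the 923 genes lower under sCAG were among 11490 genes of at least 1 CPM. Those values are thus too low, by an amount not measured here, and the excess in opposite directions may come from that. With 2 control libraries the controls could not be split into parts of at least 2 libraries, so part of the excess of shared calls may come from the shared sNT8 libraries. Without sNT8 replicate 1 r was 0.561 and without sNT8 replicate 2 it was 0.546.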

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

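Tests added after the data had been seen were edgeR with default scaling, edgeR with the replicate block, the minimum of 10, the exchanged numbering and the correlation against different sNT8 libraries among genes of at least 4 CPM; the cause of a change was not tested unless stated. A fold change of at least 2 leaves 122 genes for sCAG, 148 for sG5C and 320 for sG5C against sCAG by its construction. With all libraries kept, counts of called genes otherwise stayed within 1.5 times of the reported ones for sG5C and for sG5C against sCAG, from 1574 to 3175 and from 2636 to 4637, and for sCAG from 1150 to 1993 except with the replicate block, which gave 2724 by limma (1373 higher, against 723 without it) and 1553 by edgeR (601 higher). Nothing in the labels says that replicate numbers pair the libraries, and deviations of same-numbered libraries correlated at -0.184 for sNT8 with sG5C, 0.187 for sNT8 with sCAG and -0.133 for sG5C with sCAG, or -0.388, 0.387 and -0.353 among genes over a log2 CPM of 5. The principal component with 15.3% of the variance set replicate 1 of sNT8 and sCAG and replicate 2 of sG5C against the others, so a batch shared by those libraries is not excluded. The exchanged numbering gave 3175 calls for sG5C and 4637 for sG5C against sCAG. Leaving out 1 library, so that the lone sample is assumed to vary like the other group, gave 773 to 1847 calls for sCAG, 1209 to 2218 for sG5C and 2300 to 3819 for sG5C against sCAG. Lists past the threshold went from 7, 7 and 8 to 0, 0 and 0 with an estimated correlation (0 at an unadjusted p under 0.05 in each) and to 0, 0 and 2 by fry (3, 1 and 9 unadjusted), and to 4 to 11, 4 to 7 and 7 to 9 with 1 library left out. Under the block 20 of the 22 list calls held, the exceptions being the small RNA pathway under sG5C (adjusted p = 0.111) and extracellular matrix genes in sG5C against sCAG (0.0510). The correlation of responses was 0.188 among genes of at least 4 CPM, -0.00108 and 0.00996 against different sNT8 libraries (0.0788 and 0.0418 among genes of at least 4 CPM), and 0.325 to 0.561 with 1 library left out. Of 1161, 1389 and 180 values of called named genes under alternatives, 110, 145 and 0 lost the call and 0 reversed, and 40 of 73, 44 of 82 and 10 of 10 genes passed in every alternative. The planned test of CTG repeats in mouse transcripts was not run, since human transcripts were given, and the human ortholog was used instead. Depth limits genes near the floor, such as Fcgr3 and Mx1.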

Other observations

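The tests of CTG runs, leucine runs, GC content and hexamers were chosen only after the gene responses had been seen, whereas both tests on cholesterol synthesis were set before their results; the genes named in the next paragraph were chosen after their values were seen.

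Ptbp1 and Ptbp2 moved in opposite directions under sCAG. Ptbp1, whose product represses Ptbp2 by changing its splicing, fell from 4937 ± 94.6 to 2413 ± 49.4 normalised reads (SD, n = 2; log2 fold change -1.03, limma adjusted p = 1.4e-13), while Ptbp2 rose by 1.16. Under sG5C neither was called (-0.02 and 0.04). Single hosts of small nucleolar RNAs, which were not tested as a group, fell under sG5C: Gas5 by 0.97, Zfas1 by 1.15, Snhg1 by 0.68, Snhg5 by 1.09, Snhg8 by 1.03 and Snhg12 by 1.11, all called by limma, whereas Snhg15 and Snhg20 were not called (0.04 and -0.02). Of the former, Snhg5 and Snhg12 were also lower under sCAG, by log2 fold changes of -0.32 and -0.55, and all 6 were lower under sG5C than under sCAG, by -0.45 for Snhg1 to -0.93 for Zfas1. Hmga2, a known target of let-7 microRNAs, rose by 0.80 under each short RNA, with no call between them (log2 difference 0.02, limma adjusted p = 0.87). Foxm1, a transcription factor gene of mitosis, fell by 0.84 under sG5C and was not called under sCAG (0.08). The microRNA gene Mir6236 varied like Lars2 between the sNT8 libraries, at 347 and 2574 normalised reads in the table with sCAG.

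Genes whose human ortholog carries a run of CTG units in its transcript fell more often under sCAG: 7.10% of 8185 genes with runs of up to 2 units were lower, 12.8% of 1543 with 3, 24.3% of 210 with 4, 27.8% of 54 with 5 and 27.5% of 51 with at least 6, against 11.1%, 17.2%, 16.3%, 14.55% and 9.80% lower under sG5C, while 9.80% of those with at least 6 were higher under sCAG against 6.89% with up to 2, and the 14 with at least 8 lay -0.148 lower in median than other genes (permutation p = 0.033, 0.051 adjusted over 15 tests). Carriers of at least 6 units differed in median from other genes by -0.1175 under sCAG (permutation p = 0.0017, 0.00364 adjusted). Under sG5C the difference was 0.0605 (permutation p = 0.14, 0.175 adjusted). Under sCAG minus sG5C it was -0.212 (permutation p = 6e-05, 0.0004 adjusted). Under sCAG within classes of coding GC and expression it was -0.114 (permutation p = 0.0024, 0.0045 adjusted). This argues against coding GC and expression as the whole cause. Among genes with a leucine run of at least 5, those with at least 4 CTG units lay -0.176 below those with under 3 (permutation p = 0.00067, 0.00168 adjusted), although leucine-run genes with under 3 CTG units were themselves lower by -0.0919 (p = 0.00027, 0.00101 adjusted), and without a leucine run of 4 the CTG difference was -0.0259 (p = 0.25, 0.268 adjusted). Of all hexamers in 3' UTRs, GCTGCT had the lowest t under sCAG (-5.363, coefficient -0.0385), against a coefficient of 0.0137 for its reverse complement AGCAGC. The next, TGCTGC, had -0.0377 against 0.0115 for GCAGCA. Both hexamers overlap each other and were picked as the lowest of all. Higher coefficients of their reverse complements may therefore come in part from that choice. The strand difference of these hexamers was not tested. Counted anywhere in the transcript, CAG runs of at least 6 units went with lower values too, by -0.0897 under sCAG (permutation p = 0.0004, 0.0012 adjusted). Under sG5C that difference was -0.0590 (permutation p = 0.034, 0.051 adjusted). Pairing of sCAG with CTG runs may contribute, as a hypothesis from human sequence. Leucine runs remain an alternative, since no CTG difference was found among genes with a leucine run under 4. The length of the leucine run was not matched in the test among leucine-run genes, so that test cannot separate the 2. Sephs2 and Itgav fell although their human orthologs have runs of only 2 units. Their mouse transcripts were not examined, so sites in those are not excluded.

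Genes whose human ortholog has a GC-rich coding sequence fell more often under sG5C. Of 5 classes by coding GC, 4.11% were lower in the lowest and 20.7% in the highest. Across genes coding GC correlated with the log2 fold change at r = -0.205, against -0.0337 under sCAG. A GC trend between single libraries cannot be told apart from this. The sNT8 replicates differed by a slope of 0.0556 per 10 points of coding GC, and sG5C libraries against sNT8 libraries by -0.0389 to -0.115. Adjusted for length and GC of the 3' UTR, 40 hexamers with at least 4 C in a row had a mean coefficient of -0.0363 under sG5C and their reverse complements one of -0.0228 (difference -0.0136, permutation p = 8e-05, 0.0004 adjusted, lower for 34 of 40), against -0.00254 under sCAG (p = 0.43). Both strands thus went with lower values beyond that adjustment, which was not explained here, and pairing with C runs may add to it, as a hypothesis.

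Of 25 cholesterol synthesis genes limma called 21 lower under sCAG and 9 under sG5C, where 16 did not pass, and the calls under sG5C were 5 and 4 without sG5C replicate 1 and 2. By camera with an estimated correlation the list had an adjusted p = 0.95 under sCAG and an adjusted p = 0.93 under sG5C (unadjusted 0.054 and 0.24). That setting also missed a simulated list shifted by -0.45 (adjusted p = 0.118 and 0.108). Taken against single sNT8 libraries, the medians were -0.458 and -0.458 for sCAG and -0.166 and -0.207 for sG5C. At least 18 of 25 members were below 0 each time. This argues against a chance value of a single sNT8 library as the source, but cannot exclude a deviation common to both. Only 1 of the 25 members had an ortholog with a run of at least 4 CTG units, with a log2 fold change of 0.886 under sCAG. The other 24 had a median of -0.484, so runs of that length do not account for the fall. Shorter runs were not tested within the list. No biological explanation was tested.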
